A study of Streptomyces coelicolor with 6 samples.

How the data were processed

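RNA of Streptomyces coelicolor M145 and of a wblA deletion mutant was measured on spotted oligonucleotide arrays in 72 hybridisations, each with labelled RNA in channel 1 and labelled M145 genomic DNA, a common reference, in channel 2. The 6 deposited samples were 6 times of growth on cellophane over solid minimal medium with mannitol (24, 36, 48, 60, 72 and 84 h). Per the labels, each time held 3 cultures of each strain (biological replicates) and 2 arrays of each culture (technical replicates), so that 36 cultures in 12 groups of 3 were compared. The labels give the time of each deposited sample, while the strain, the culture number and the array number of each array came from the names of the deposited array files; wblA itself was used to check the strain.

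The deposited array files hold spot intensity per channel on a linear scale, per the file headers from BlueFuse for Microarrays 3.1, which modelled the background and scaled the channels to each other by block median. The confidence and presence values of each spot are a score between 0 and 1 from the same software, per the file headers. A deposited value table holds log2 values of unstated scale, centring and direction, 1 column per time. Its column medians were 0.03, 0.02, -0.06, -0.10, -0.00 and -0.01 from 24 to 84 h. Set against the array files, the table followed the log2 difference of mutant minus M145 (r over genes 0.879 at 24 h and 0.940 at 36 h, slopes 0.919 and 0.996), so direction, log base and scale were settled there; how the authors centred it stays unknown. Its lines were matched to genes by the sorted order of the 8004 identifiers with 2 spots, a match that rests on these correlations. At 48 to 84 h the table followed the array files less closely, and its values for single genes are not given. The tool limma is named in the submitters' processing notes; its role there is not given in the sources used here. The label fields put RNA in Cy5 and the protocols put it in Cy3. The channel was settled from the values, since probes for 16S ribosomal RNA lay above the median gene in channel 1 (median over arrays 3.81 on the log2 scale) and below it in channel 2 (median -1.48). In channel 1 the value ran from 0.095 (a mutant array at 72 h) to 5.65 (an M145 array at 84 h). At each time its mean over arrays was lower in the mutant than in M145, with arrays of the strains overlapping. Whether it differed between the strains was not tested.

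Each array had 18240 spots, 2228 of them controls. The analysis used 7727 chromosomal gene identifiers (SCO numbers), each with 1 probe in 2 spots apart from 1 identifier. A further 278 probes for the plasmid SCP1, which M145 lacks, were kept for background. Per spot, log2 of the RNA intensity over the DNA intensity was taken with no further background correction, arrays were centred on the median and quantile-normalised to each other, spots of a gene were averaged, and the 2 arrays of a culture were averaged. No loess within arrays was applied, because with a near-constant DNA channel the ratio rises with brightness for every expressed gene. A level is thus a log2 ratio to genomic DNA, 0 being close to the median gene. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, over all 12 groups, which shared 1 estimate of the spread), with Benjamini-Hochberg adjustment over 7727 genes and a threshold of 0.05. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used to read files and to draw figures. The comparisons were mutant against M145 at each of the 6 times, the mean of the 6 differences, an F test of whether the difference changed between times, and an F test of time within each strain. Folds are given only as bounds, and for part of the genes. For these the RNA of the dimmer group was raised, where lower, to the 95th percentile of the negative controls of its array, and the ratio was taken again. No bound is given where it was not above 1, or where the brighter group exceeded that level on no array or the dimmer on some. The rule was chosen after the data were seen.

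Before the data were examined, the comparisons, the alternatives, all gene lists but 1 and the rule for naming genes were fixed. The rule took wblA with its 2 neighbours on each side, the 5 largest changes each way at each time whose 3 cultures did not overlap, the 10 largest each way on average and in M145 at 84 h, up to 4 members past the threshold per list, 5 pathway regulators, all chaplin, SapB, bld and whi genes, and the 10 smallest p of the F test between times. It gave 135 genes in 511 entries. Gene names are those of the fixed lists. The files pair SCO numbers with no names and none of the 7842 rows of the reference table carried an SCO number (0 matched), so genes outside the lists appear by number, at most 2 each way per comparison. A ribosomal list by annotated product could not be formed for the same reason, and the S10-spc block of ribosomal protein genes was chosen in its place after seeing the files. Lists were tested with camera (correlation preset at 0.01, then estimated) and with fry, adjusted over the 24 lists. Fry, which tests whether the members of a list move on balance one way, is not used for calls.

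Array medians of RNA intensity ran from 117.7 to 744.6 (median 315.4) and of DNA intensity from 132.2 to 955.3. The presence score did not separate signal from background and is not used: RNA was scored as present (at least 0.5) on 90.6% of gene spots, 90.4% of SCP1 spots and 60.0% of negative control spots, and in both wblA spots on every mutant array. Over all arrays the median gene had an RNA intensity of 322, the negative controls 241 and the SCP1 probes 209, so low transcripts were close to background and their differences are compressed. The number of cultures limits the precision. The 2 arrays of a culture correlated over genes at r = 0.685 to 0.919 and cultures within a group at 0.782 to 0.918; genes are not independent replicates. The dates in the file headers took 4 values, which are called array batches here. Culture 1 of both strains lay in batch 1 at all times, and cultures 2 and 3 lay in batches 2 and 3 at 24 and 36 h. From 48 h on M145 cultures 2 and 3 lay in batch 4, with the mutant's spread over batches.

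The culture numbers pair the strains where same-numbered cultures of a time deviate together. The deviations of the 18 pairs correlated over genes at 0.00595 to 0.761 (median 0.414), and 17 were above 0.1. Every pair was above it at 5 times, and culture 2 at 84 h was not. The numbers were therefore read as pairs from 24 to 72 h but not at 84 h or over all times. As fixed in advance, the values given come from the fit without pairs. The paired fit is an alternative, given beside a result from 24 to 72 h where it ended a call. The pairing comes from the file names. Same-numbered cultures of the strains shared an array batch at 24 and 36 h, and culture 1 did at all times, so pairing and batch cannot be told apart there. What else the cultures shared is not given in the sources used here.

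The steps were tested on simulated data built from the real levels and spread of 7727 genes, with 100 genes changed 2-fold and 100 changed 4-fold per comparison. Of the 2-fold changes, 36, 27, 41, 27, 33 and 34% were recovered at 24 to 84 h, 91% on average over times, 7% in the test between times and 27 and 39% over time in M145 and the mutant. Of the 4-fold changes, 86, 75, 81, 80, 80 and 81% were recovered at 24 to 84 h, 99% on average, 60% between times and 88 and 76% over time. False calls made up 1.04% (average) to 10.7% (between times) of calls, and of the 24 lists the 1 shifted list was called and 0 others. The simulated noise was independent between genes and cultures, without batch, pairing or correlated genes. These rates therefore cannot be taken as those of the real data.

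Alternatives were median centring only, equal-spread scaling, loess first, the RNA channel alone, low-confidence spots (below 0.1) or the dimmest genes (lowest 0.25 by RNA intensity) left out, all arrays with culture as a random block, each array of a culture alone, array weights, the pairing of cultures as a block, array batch as a covariate, a 2-fold minimum, only the 6 cultures of a time, the deposited table, and each culture left out in turn. Chosen after seeing the data were slide series as a covariate, the mean difference within each batch and at 24 and 36 h alone, batch, pairing and each culture left out for gene lists, and the fit without 4 doubted arrays. Control and SCP1 spots were left out of all comparisons of genes.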

Results

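Transcript levels of Streptomyces coelicolor M145, a prototrophic laboratory strain of a filamentous, sporulating and antibiotic-producing soil bacterium, were set beside those of a strain lacking wblA, which encodes a protein of the WhiB-like family of actinobacterial regulators. Per the design text, the 6 times of growth on solid medium (24, 36, 48, 60, 72 and 84 h) spanned vegetative growth, the growth of aerial hyphae and sporulation. Each strain and time had 3 cultures with 2 arrays each, 72 arrays in all. Array medians of RNA intensity lay between 117.7 and 744.6. Levels are log2 ratios of RNA to M145 genomic DNA, differences are mutant minus M145 on the log2 scale with the limma SE, and at a single time n = 3 cultures per strain. They are differences of signal: in 152 of 161 named calls between 2 groups the dimmer group exceeded 95% of the negative controls on no array, and in 62 of these neither group did. A fold is therefore given only as a bound, with the dimmer group taken at that level.

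The deleted gene was read first. In the 18 mutant cultures wblA (SCO3579) lay between -0.96 and -0.29 (mean -0.62, SD 0.20), and in the 18 M145 cultures between 0.88 and 4.20 (mean 2.28, SD 0.80), so that no culture went against its strain. The difference was -2.76, -2.46, -3.46, -2.88, -2.42 and -3.39 from 24 to 84 h (SE 0.45 at each time) and -2.90 ± 0.18 on average (adjusted p = 1.01e-11). On the mutant arrays its RNA intensity was 42.0 to 123, below the median of 241 of the negative controls, so no fold is given. Single arrays of 4 M145 cultures had a wblA signal near that of the mutant, and each of these cultures also rests on its other array. Of the neighbouring genes on average over times, SCO3577 was lower by a difference of -0.47 (adjusted p = 0.000196) and SCO3581 by -0.25 (adjusted p = 0.0388), while SCO3578 (-0.19) and SCO3580 (0.20) did not pass. Which part of the gene was deleted is not given in the sources used here.

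**Figure D1:**
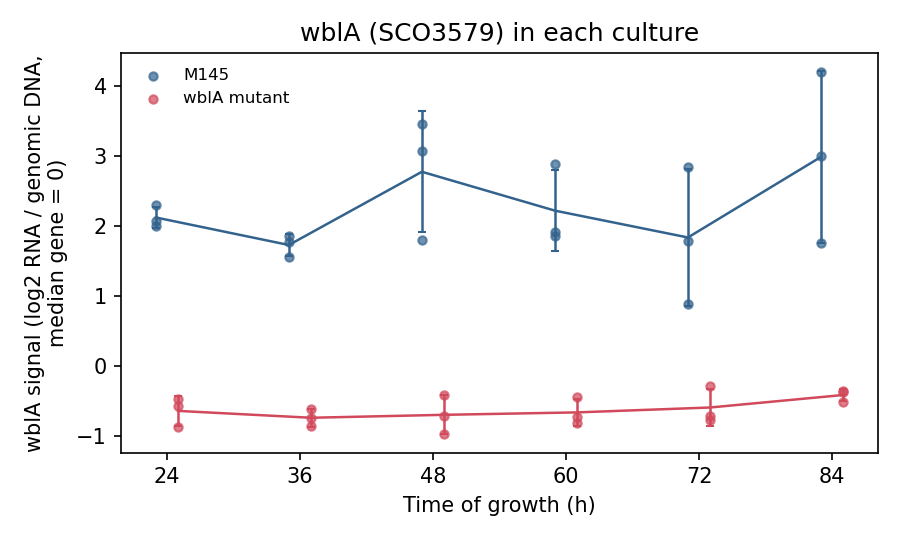
Signal of wblA (log2 RNA over genomic DNA, y axis) against time of growth in h (x axis) in M145 and the wblA mutant; points are cultures, lines are means of 3 cultures and bars are SD. All mutant cultures lie between -0.96 and -0.29 and all M145 cultures between 0.88 and 4.20.

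At 24 h the question was which genes differed between the strains at the earliest time. Genes of the chaplins and rodlins, hydrophobic proteins that coat aerial hyphae and spores, were lower in the mutant: chpE by -2.91 ± 0.59 (at least 2.25-fold, adjusted p = 0.0247) and chpA by -1.62 ± 0.30 (adjusted p = 0.0102). These were 2 of the 11 measured members of that list, and 6 fell when adjusted over the list alone (camera adjusted p = 1e-14, 0.0188 with an estimated correlation). Outside the lists, SCO1628 (-3.07 ± 0.50) and SCO4237 (-2.65 ± 0.35) were lower, and the only gene that rose was SCO7466 (1.39 ± 0.25, adjusted p = 0.00694).

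As lists at 24 h, the biosynthetic clusters of the blue antibiotic actinorhodin and of the calcium-dependent antibiotic lay higher (camera adjusted p = 0.00741 for each), with no single member past the threshold in limma. Both calls were lost (adjusted p = 0.422 with an estimated correlation for each), as they were with the RNA channel alone. Gas vesicle genes lay lower (camera adjusted p = 0.00741, 0.0319 with an estimated correlation, 1 of 20 adjusted over the list alone), a call that loess normalisation and the RNA channel alone both ended. Each of these 3 calls also ended when 1 culture was left out, such as mutant culture 1 for actinorhodin (adjusted p = 0.14).

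In all, 12 of 7727 genes passed the threshold at 24 h, 11 lower and 1 higher in the mutant, and 274 had an unadjusted p under 0.05. All 12 had cultures of the strains that did not overlap. This held for 872 of all genes (11.3%, where chance gives 10%). With array batch as a covariate 28 genes passed, with array weights 92 and with only the 6 cultures of this time 3, and leaving out M145 culture 2 left 5. Gene counts with batch as a covariate, here and below, came from a fit on single arrays. It counted the 2 arrays of a culture almost as separate replicates, so higher counts cannot be read as gained by adjusting for batch.

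At 36 h chpD was lower in the mutant, at least 5.46-fold (-4.32 ± 0.63, adjusted p = 0.000247). The chaplin chpA (-1.85 ± 0.30, adjusted p = 0.00121) and the spore coat gene nepA (-1.65 ± 0.36, adjusted p = 0.0223) fell as well, as did sigF, a sigma factor of late sporulation (-1.36 ± 0.25, adjusted p = 0.00303). In the opposite direction, the actinorhodin genes SCO5071 (4.07 ± 0.70) and SCO5076 (3.15 ± 0.56, at least 1.78-fold) were higher in the mutant. Genes of the coelimycin cluster, which makes a yellow polyketide, rose with them: SCO6282 by 2.34 ± 0.56 (at least 1.98-fold, adjusted p = 0.037) and SCO6277 by 1.62 ± 0.33 (adjusted p = 0.0104).

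By list at 36 h, 3 of 22 actinorhodin genes rose (9 adjusted over the list alone; camera adjusted p = 3.03e-11, 0.0475 with an estimated correlation) and 2 of 17 coelimycin genes rose (9 adjusted over the list alone; camera adjusted p = 4.66e-11, 0.00435 with an estimated correlation). The 10 nitrogen assimilation genes lay higher (2 adjusted over the list alone; camera adjusted p = 1.14e-05, 0.0475 with an estimated correlation). Of the chaplins and rodlins 3 of 11 fell (6 adjusted over the list alone; camera adjusted p = 4.66e-11, 0.0258 with an estimated correlation). Of 20 gas vesicle genes 3 fell, among them SCO0650 (-2.33 ± 0.45) and SCO0654 (-2.05 ± 0.40), with 4 adjusted over the list alone (camera adjusted p = 0.000276, 0.0048 with an estimated correlation), though the RNA channel alone ended the call of the list. The whi genes, regulators of sporulation, lay lower (1 of 9 over all genes, 2 adjusted over the list alone; camera adjusted p = 0.0188, 0.0475 with an estimated correlation), which was lost when cultures were paired (0.0678) and with the RNA channel alone (0.0621). Septation genes fell in 2 of 25 cases, among them sffA (-2.22 ± 0.55) and mbl (-1.11 ± 0.24), also 2 adjusted over the list alone, with camera adjusted p = 0.0118 but adjusted p = 0.128 with an estimated correlation. Calcium-dependent antibiotic genes lay higher and the S10-spc block of ribosomal protein genes lower (camera adjusted p = 0.000563 and 0.000324), and each had adjusted p = 0.233 with an estimated correlation. The whi and septation calls also ended without M145 culture 1 (0.0524 and 0.0742). For SCO0654 and mbl neither strain exceeded the median negative control on any array.

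Among 77 genes past the threshold at 36 h, 41 were higher and 36 lower in the mutant, and 631 had an unadjusted p under 0.05. The strains did not overlap in 76 of the 77, and in 1154 of all genes (14.9%, where chance gives 10%). Outside the lists, changes were seen in SCO1195 (-2.73 ± 0.40), SCO4237 (-2.44 ± 0.35), SCO0762 (2.69 ± 0.44) and SCO4253 (2.24 ± 0.54; adjusted p = 0.0592 with cultures paired). With cultures paired 122 genes passed, with array batch as a covariate 263, with array weights 485, with the RNA channel alone 43 and with only the 6 cultures of this time 22. Leaving out 1 culture gave from 26 (without mutant culture 2) to 125 (without mutant culture 1).

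At 48 h the mutant had lower chpD (-4.10 ± 0.63, at least 6.52-fold), chpE (-3.36 ± 0.59, at least 4.99-fold) and chpA (-2.58 ± 0.30, at least 3.07-fold). Also lower were nepA (-2.17 ± 0.36) and the rodlin genes rdlA (-2.03 ± 0.49) and rdlB (-1.81 ± 0.45). The sporulation regulator whiB was lower (-2.08 ± 0.46, adjusted p = 0.0143), and the septation genes sffA (-2.63 ± 0.55), ssgB (-1.36 ± 0.34) and mbl (-1.32 ± 0.24) fell. Actinorhodin genes were again higher, SCO5071 by 5.17 ± 0.70 (at least 1.47-fold, adjusted p = 5.26e-05) and SCO5076 by 3.70 ± 0.56 (at least 4.23-fold).

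Of the chaplins and rodlins 6 of 11 fell at 48 h (9 adjusted over the list alone; camera adjusted p = 3.78e-18, 0.00634 with an estimated correlation), and of the whi regulators 1 of 9 (3 adjusted over the list alone; 0.00166, 0.0177 with an estimated correlation). Actinorhodin genes rose in 4 of 22 cases, 1 of which did not pass with cultures paired (11 adjusted over the list alone, camera adjusted p = 9.2e-14, 0.0394 with an estimated correlation). The whiE spore pigment genes SCO5316 (-2.04 ± 0.52) and SCO5320 (-1.28 ± 0.32) fell, 2 of 8 (2 adjusted over the list alone; camera adjusted p = 0.00313), and 3 of 25 septation genes (4 adjusted over the list alone; 0.00112), yet each had adjusted p = 0.0589 with an estimated correlation. Calcium-dependent antibiotic genes lay higher (1 of 40, 4 adjusted over the list alone; camera adjusted p = 2.63e-07; adjusted p = 0.0761 with an estimated correlation), as did coelimycin genes (0 of 17 in limma, 0.00195; adjusted p = 0.0809 with an estimated correlation). The bld regulators of aerial growth, ATP synthase, NADH dehydrogenase and desferrioxamine lists (camera adjusted p = 0.0188, 0.000357, 0.00112 and 0.0175, the last one higher and the others lower) each had adjusted p = 0.0783 with an estimated correlation. ATP synthase genes numbered 4 of 9 and desferrioxamine genes 2 of 4 adjusted over the list alone, and the bld and desferrioxamine calls were lost with batch as a covariate, the latter also with the RNA channel alone. Both also ended without M145 culture 3 (0.113 and 0.0948). The S10-spc block lay lower (camera adjusted p = 0.000164; adjusted p = 0.149 with an estimated correlation). Gas vesicle genes had a call of 0.0342 (adjusted p = 0.0783 with an estimated correlation) and a median of -0.02 that turned to 0.12 with the RNA channel alone; 2 of 20 fell, among them SCO0654 (-1.62 ± 0.40), and the call ended without M145 culture 1 (0.13). The catalase gene katB was lower (-1.96 ± 0.50), with neither strain above the median negative control on any array.

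At 48 h 109 genes passed the threshold, 74 lower and 35 higher in the mutant (679 with an unadjusted p under 0.05), of which 108 had cultures that did not overlap between strains (903 of all genes, 11.7%, where chance gives 10%). Outside the lists, SCO0834 (-3.66 ± 0.45) and SCO7434 (-3.30 ± 0.58) fell and SCO5845 (2.76 ± 0.51) and SCO1578 (2.69 ± 0.68) rose. With cultures paired 178 genes passed, with array batch as a covariate 217, with array weights 168, with the RNA channel alone 59 and with only the 6 cultures of this time 0 in limma. Leaving out M145 culture 2, mutant culture 2 or mutant culture 3 gave 57, 58 and 61.

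At 60 h the pathway activator actII-ORF4 passed the threshold along with its actinorhodin cluster: it was at least 1.88-fold higher in the mutant (2.40 ± 0.55, adjusted p = 0.0175). SCO5071 rose by 4.86 ± 0.70 (at least 1.69-fold), SCO5076 by 4.15 ± 0.56 and SCO5080 by 3.70 ± 0.58 (at least 1.66-fold). Lower in the mutant were chpD (-3.94 ± 0.63, at least 4.77-fold), sffA (-2.87 ± 0.55), nepA (-2.14 ± 0.36), whiB (-1.79 ± 0.46) and bldN, a sigma factor for aerial growth (-1.70 ± 0.43, adjusted p = 0.0343).

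By list at 60 h, 10 of 22 actinorhodin genes rose (15 adjusted over the list alone; camera adjusted p = 5.32e-21, 0.00854 with an estimated correlation). Of the chaplins and rodlins 5 of 11 fell (8 adjusted over the list alone; 3.91e-13, 0.012 with an estimated correlation), and of the gas vesicle genes 3 of 20, with SCO0650 at -2.46 ± 0.45 (5 adjusted over the list alone; 0.000425, 0.00854 with an estimated correlation; call lost with the RNA channel alone, where SCO6505 turned from -0.75 to 0.04). Septation genes fell in 2 of 25 cases and 4 adjusted over the list alone (camera adjusted p = 0.00679). Lists that lay higher were the calcium-dependent antibiotic (1 of 40, 10 adjusted over the list alone; 1.26e-06), SapB, a surface peptide of aerial growth (2 of 5 adjusted over the list alone; 0.0274), and desferrioxamine (1 of 4 adjusted over the list alone; 0.0114). These 4 lists each had adjusted p = 0.0867 with an estimated correlation, and the septation, SapB and desferrioxamine calls were also lost with batch as a covariate and with the RNA channel alone. The 1 calcium-dependent antibiotic gene past the threshold did not pass with cultures paired. Coelimycin and nitrogen assimilation genes lay higher too (camera adjusted p = 0.0271 and 0.00959), each with adjusted p = 0.223 with an estimated correlation. The coelimycin call was also lost with batch as a covariate (0.0903) and with the RNA channel alone (0.0591). When 1 culture was left out the calls of the septation (0.0677 without mutant culture 1), SapB, desferrioxamine, coelimycin (each 0.104 without M145 culture 3) and nitrogen assimilation lists (0.0652 without M145 culture 1) ended. In the vegetative glycogen cluster SCO5444 was lower (-1.40 ± 0.35), but higher by 0.35 with the RNA channel alone.

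At this time 148 genes passed the threshold, 78 lower and 70 higher in the mutant (786 with an unadjusted p under 0.05), and in 147 of them the strains did not overlap (1186 of all genes, 15.3%, where chance gives 10%). Outside the lists SCO0834 (-3.97 ± 0.45, at least 2.27-fold) and SCO0833 (-3.96 ± 0.49) were lower and SCO5845 higher (SE 0.51, adjusted p = 0.000475). With cultures paired 240 genes passed, with array batch as a covariate 290, with array weights 1012, with the RNA channel alone 67 and with only the 6 cultures of this time 31. Without M145 culture 2 or 3 the count was 83 and 73, and without mutant culture 2 or 3 it was 65 and 71.

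At 72 h 9 of the 35 genes that rose in the mutant were actinorhodin genes: among them were SCO5071 (3.86 ± 0.70), SCO5076 (3.45 ± 0.56), SCO5080 (2.62 ± 0.58; adjusted p = 0.0931 with cultures paired) and SCO5073 (2.47 ± 0.47, at least 1.28-fold). Of the 22 genes of the list 9 rose, and 13 adjusted over the list alone (camera adjusted p = 3.32e-23, 0.00922 with an estimated correlation). Of the chaplins and rodlins, chpA alone fell over all genes tested (-1.50 ± 0.30, adjusted p = 0.0101), and 2 of 11 adjusted over the list alone (camera adjusted p = 3.88e-07; adjusted p = 0.114 with an estimated correlation). Gas vesicle genes lay lower (1 of 20 adjusted over the list alone; 0.00131, 0.00922 with an estimated correlation), a call lost with the RNA channel alone. Septation genes lay lower (1 of 25 adjusted over the list alone; camera adjusted p = 0.00496; adjusted p = 0.114 with an estimated correlation), as did genes of oxidative and sigma-B stress (2 of 8 adjusted over the list alone; 0.0194; adjusted p = 0.268 with an estimated correlation), whose call also ended after loess, with the RNA channel alone and with batch as a covariate. Nitrogen assimilation genes (0.00496; adjusted p = 0.292 with an estimated correlation) and the S10-spc block (0.0427; adjusted p = 0.528 with an estimated correlation) lay higher, the latter not with median centring only (0.0881) or with the RNA channel alone (0.127). The mean of the S10-spc block went from 0.30 to 0.00 without mutant culture 1. Without that culture the septation, stress and nitrogen assimilation calls ended too (0.0937, 0.153 and 0.0937), and the gas vesicle call ended without M145 culture 1 (0.069).

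The threshold was passed by 59 genes at 72 h, 24 lower and 35 higher in the mutant (592 with an unadjusted p under 0.05), 58 of them with strains that did not overlap (765 of all genes, 9.90%, where chance gives 10%). SCO0834 was at least 3.95-fold lower (-4.81 ± 0.45, adjusted p = 2.12e-07) and SCO0838 at least 1.97-fold lower (-3.14 ± 0.50), while SCO5845 (2.66 ± 0.51) and SCO5259 (2.56 ± 0.46) rose. With array batch as a covariate 155 genes passed, with array weights 39, with the RNA channel alone 22 and with only the 6 cultures of this time 1. Without M145 culture 2 or 3 the count was 38 and 23, and without mutant culture 1 or 3 it was 26 and 12.

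At 84 h, the last time, the mutant had more SCO5080 (4.66 ± 0.58, at least 1.86-fold, adjusted p = 1.09e-05), SCO5071 (4.46 ± 0.70, at least 1.35-fold) and SCO5088 transcript (3.71 ± 0.39, at least 3.65-fold), all of the actinorhodin cluster, and more of its activator actII-ORF4 (2.15 ± 0.55, at least 1.51-fold, adjusted p = 0.0268). For actII-ORF4 the strains overlapped, with mutant culture 2 at 0.80 and M145 culture 1 at 0.85. The gene ramS, which encodes the SapB precursor, was at least 1.38-fold higher (3.12 ± 0.77, adjusted p = 0.0194). Lower in the mutant were chpD (-3.35 ± 0.63, at least 4.14-fold), sffA (-2.27 ± 0.55), chpA (-1.94 ± 0.30, at least 1.41-fold) and the stress genes sigB (-1.19 ± 0.29), dpsA (-1.10 ± 0.24), which encodes a nucleoid protein, and trxC (-1.03 ± 0.23).

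By list at 84 h, 15 of 22 actinorhodin genes rose (16 adjusted over the list alone; camera adjusted p = 6.58e-25, 0.00701 with an estimated correlation). This was the only list of the 24 whose call held with an estimated correlation at 84 h. Chaplins and rodlins (2 of 11 fell, 8 adjusted over the list alone; camera adjusted p = 5.47e-09), septation genes (3 of 25, 6 adjusted over the list alone; 0.00158) and undecylprodigiosin genes of the red antibiotic (1 of 22 rose, SCO5891 at 1.02 ± 0.18, 2 adjusted over the list alone; 0.00467) each had adjusted p = 0.054 with an estimated correlation. Stress genes fell in 3 of 8 cases (4 adjusted over the list alone; 0.00467) and NADH dehydrogenase genes rose in 2 of 14 (6 adjusted over the list alone; 0.00158), each with adjusted p = 0.116 with an estimated correlation. The NADH dehydrogenase list rested on mutant culture 3 (1.59, where the other 5 cultures lay between 0.60 and 0.76), without which its mean difference went from 0.34 to 0.06 (adjusted p = 0.183). Of the gas vesicle genes SCO0651 fell (-0.69 ± 0.17; 2 of 20 adjusted over the list alone; camera adjusted p = 0.0409; adjusted p = 0.081 with an estimated correlation; 0.171 without M145 culture 1). The calls of the septation, stress, NADH dehydrogenase and gas vesicle lists were lost with the RNA channel alone.

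At 84 h 225 genes passed the threshold, 100 lower and 125 higher in the mutant (978 with an unadjusted p under 0.05). The strains did not overlap in 215 of the 225 and in 979 of all genes (12.7%, where chance gives 10%). Outside the lists SCO0834 was at least 6.73-fold lower (-5.79 ± 0.45, adjusted p = 3.18e-09) and SCO0833 lower (-4.13 ± 0.49), while SCO4425 was at least 4.32-fold higher (3.59 ± 0.64) and SCO5845 higher by 3.43 ± 0.51. With array batch as a covariate 548 genes passed, with array weights 853, with the RNA channel alone 104 and with only the 6 cultures of this time 1. Without M145 culture 2 or 3 the count was 125 and 129, and without mutant culture 3 it was 132.

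**Figure D2:**
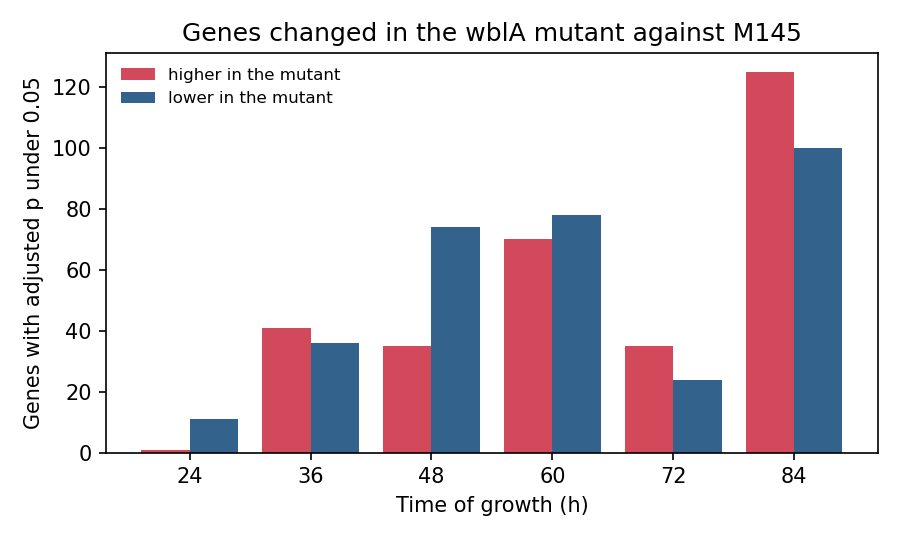
Number of genes with an adjusted p under 0.05 (y axis) higher or lower in the wblA mutant than in M145 at each time of growth in h (x axis), with 3 cultures per strain and time. The bars run from 1 higher and 11 lower at 24 h to 125 higher and 100 lower at 84 h.

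Averaged over the 6 times (18 cultures per strain), the comparison asked which genes differed in the mean of the times. The list of chaplins and rodlins, which also holds the spore coat gene nepA, fell almost as a whole, 10 of 11: chpD (-3.48 ± 0.26, adjusted p = 8.69e-11), chpE (-2.23 ± 0.24), chpA (-1.90 ± 0.12) and rdlA (-1.68 ± 0.20) among them. The genes nepA, rdlB, chpH, chpF, chpG and chpC fell by differences between -1.51 and -0.69. Of the actinorhodin genes 17 of 22 rose, among them SCO5071 (3.93 ± 0.28, adjusted p = 8.69e-11), SCO5076 (3.13 ± 0.23), SCO5080 (2.50 ± 0.24) and the activator actII-ORF4 (1.57 ± 0.23, adjusted p = 1.18e-05). The mean level of the actinorhodin list ran from 0.69 at 24 h to 0.61 at 84 h in M145 and from 1.01 to 2.63 in the mutant. That of the chaplins and rodlins ran from 1.94 to 2.16 in M145 and from 0.75 to 0.68 in the mutant. Both lists kept their direction under all 4 other scalings.

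On average over times the whi list had 3 of 9 members lower, whiB (-1.53 ± 0.19), whiH (-0.91 ± 0.18) and sigF (-0.58 ± 0.10). The bld list had 2 of 8, bldN (-1.06 ± 0.18) and rsbN (-0.69 ± 0.20), which encodes an anti-sigma factor for BldN. Septation genes fell in 6 of 25 cases, among them sffA (-2.07 ± 0.22), ssgG (-0.93 ± 0.18), mbl (-0.91 ± 0.10) and ssgB (-0.87 ± 0.14). Of the gas vesicle genes 7 of 20 fell, such as SCO0650 (-1.56 ± 0.18) and SCO0654 (-1.17 ± 0.16), but the median of that list, -0.20, turned to 0.06 with the RNA channel alone (camera adjusted p = 0.314). Spore pigment genes went both ways, with SCO5316 (-1.13 ± 0.21), SCO5317 (-0.69 ± 0.18) and SCO5320 (-0.69 ± 0.13) among 4 that fell and SCO5318 (0.86 ± 0.17) higher. Among 8 stress genes 4 fell: katB (-1.31 ± 0.21), sigB (-0.59 ± 0.12), dpsA (-0.41 ± 0.10) and trxC (-0.32 ± 0.09).

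The calcium-dependent antibiotic cluster had 12 of 40 members higher on average, such as SCO3230 (1.04 ± 0.33) and SCO3222 (0.92 ± 0.14). Its regulator gene cdaR rose as well (0.58 ± 0.15, adjusted p = 0.00767). Of the coelimycin genes 5 of 17 measured rose, SCO6282 among them (1.33 ± 0.23). The regulators redD and redZ of undecylprodigiosin and cpkO of coelimycin did not pass. For SapB ramS (1.05 ± 0.31) and ramC (0.31 ± 0.09) rose, though ramS was lower at 24 and 36 h (-0.66 and -0.44, neither past the threshold). For nitrogen assimilation nirC (0.87 ± 0.28), the regulator gene glnR (0.62 ± 0.21) and nirB2 (0.52 ± 0.16) rose, but at 84 h 6 of the 10 members of that list were negative (median -0.29, camera adjusted p = 0.224). For phosphate starvation the sensor kinase gene phoR rose (0.90 ± 0.16). Of the desferrioxamine genes, which make an iron chelator, SCO2782 (0.51 ± 0.13) and SCO2783 (0.24 ± 0.07) rose.

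With camera, 10 of the 24 lists passed on average and 4 held with an estimated correlation: actinorhodin (3.08e-21, 0.00603 with an estimated correlation; 17 adjusted over the list alone), chaplins and rodlins (3.83e-15, 0.00603; 10 adjusted over the list alone), gas vesicle (0.000175, 0.00603; 8 adjusted over the list alone) and septation (0.000202, 0.0293; 9 adjusted over the list alone). Lost with an estimated correlation were calcium-dependent antibiotic (0.000175; adjusted p = 0.178 with an estimated correlation; 13 adjusted over the list alone), coelimycin (0.000202; adjusted p = 0.0601 with an estimated correlation; 7) and nitrogen assimilation (0.00679; adjusted p = 0.196 with an estimated correlation; 4). The same held for whi (0.0235; adjusted p = 0.0569 with an estimated correlation; 3), spore pigment (0.0388; adjusted p = 0.162 with an estimated correlation; 4 lower and 1 higher) and desferrioxamine (0.0181; adjusted p = 0.104 with an estimated correlation; 3). Those 3 calls were also lost with array batch as a covariate, and spore pigment and desferrioxamine with the RNA channel alone. The spore pigment call also ended without mutant culture 1 of 24 h (0.0568).

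The other 14 lists did not pass on average. Camera's adjusted p was 0.171 for bld regulators, 0.196 for SapB, 0.246 for undecylprodigiosin (1 of 22 higher), 0.0521 for oxidative and sigma-B stress, 0.171 for phosphate starvation and 0.135 for the vegetative glycogen cluster (2 of 5 lower; of these SCO5444, at -0.67, turned to 0.19 with the RNA channel alone). It was 0.442 for NADH dehydrogenase (1 of 14 higher and 1 lower), 0.171 for ATP synthase, 0.572 for heat shock chaperones, 0.83 for the aerial glycogen cluster and for carotenoid genes, 0.597 for coelichelin, 0.442 for hopanoid genes and 0.312 for the S10-spc block, the last 7 with 0 members past the threshold in limma.

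**Figure D3:**
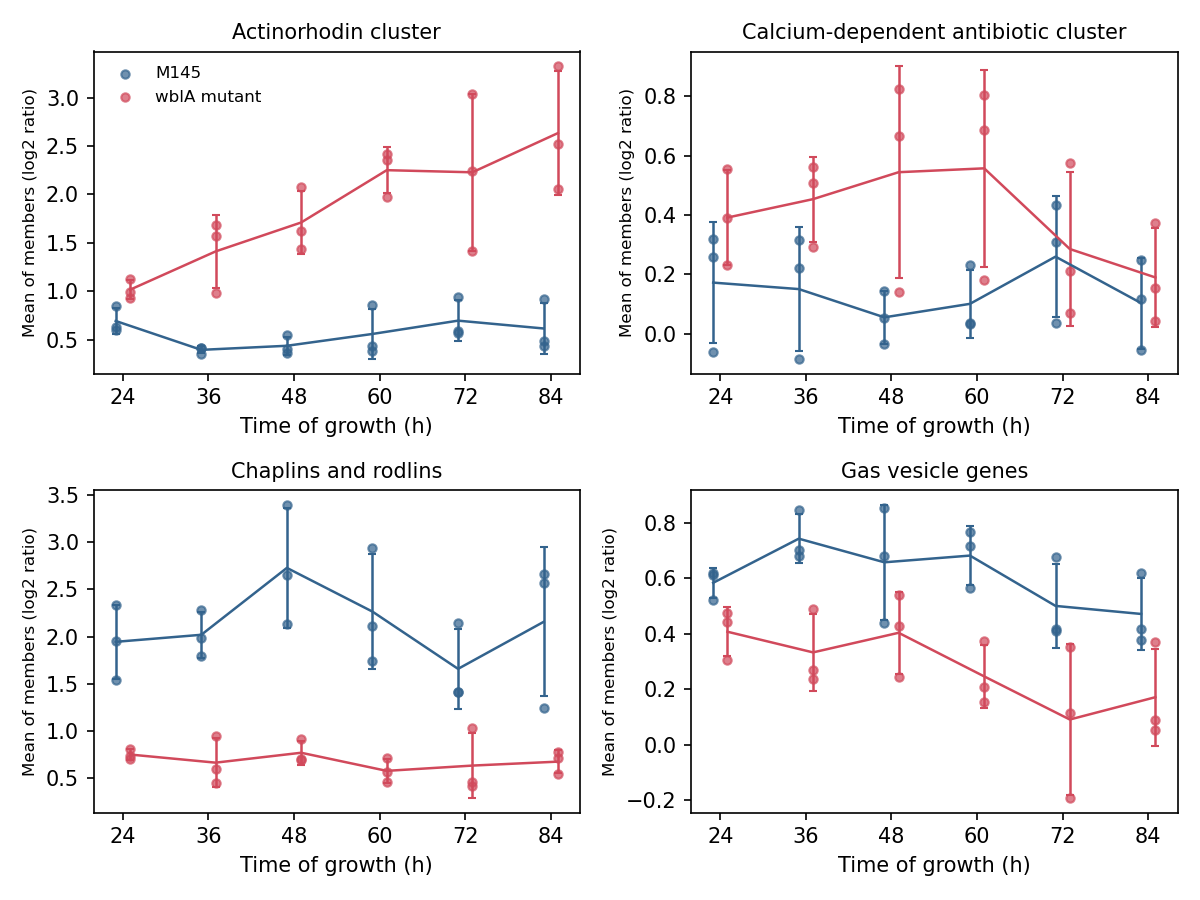
Mean level of the members of 4 gene lists (log2 ratio of RNA to genomic DNA, y axes) against time of growth in h (x axes) in M145 and the wblA mutant; points are cultures, lines are means of 3 cultures and bars are SD. The actinorhodin list reaches a mean of 2.63 in the mutant and 0.61 in M145 at 84 h; the direction of the gas vesicle list turned on average and at 48 h with the RNA channel alone.

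Of 7727 genes 1079 passed on average, 534 lower and 545 higher in the mutant, and 118 of them changed at least 2-fold by ratio (58 higher, 60 lower). In a fit that also held the 278 SCP1 probes, which have no target in M145, 16 of them passed, 2 at 2-fold or more. The sign was the same at all 6 times in 814 of the 1079. Outside the lists SCO0834 (-3.48 ± 0.18) and SCO0833 (-2.92 ± 0.20) fell, and SCO5845 (2.26 ± 0.21) and SCO0762 (2.15 ± 0.18) rose. Taking the times singly, 353 genes passed at 1 or more of them and 0 passed in both directions in limma. SCO0588, SCO1628, SCO7466, chpA and wblA passed at all 6.

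Within each of the 4 array batches alone 855, 75, 55 and 588 genes passed, and with batch as a covariate 1354 did. These fits used single arrays, and the one with the covariate counted the 2 arrays of a culture almost as separate replicates. Its count is thus not comparable with the count from culture means. Array weights gave 1897, and the first array of each culture alone 606. The batches also differed in time, since batches 2 and 3 held M145 only at 24 and 36 h and batch 4 held it only from 48 h on. The wblA difference within batches was -2.10, -2.90, -2.51 and -3.81. The median of the actinorhodin list was 1.02, 0.82, 0.69 and 2.58 and that of the chaplins and rodlins -1.15, -1.12, -0.76 and -1.71.

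Whether the difference between strains depended on time was tested with 1 F test over the 6 times. It passed for 8 genes, 7 of them outside the fixed lists: SCO0678, SCO0834, SCO2846, SCO7620 and SCO7041, whose difference moved to lower values by 84 h, and SCO4892, SCO2999 and the actinorhodin gene SCO5088, whose difference moved to higher ones. The difference in SCO0834 went from -0.64 at 24 h to -5.79 at 84 h (adjusted p = 0.00034), that in SCO0678 from 0.17 to -3.04 (adjusted p = 0.000153) and that in SCO5088 from 0.34 to 3.71 (adjusted p = 0.0242). At an unadjusted p under 0.05 the count was 274. With array batch as a covariate 109 genes passed, with array weights 212 and with the RNA channel alone 4, and without M145 culture 2 or mutant culture 1 of 84 h the count was 4 and 17. The differences in counts between times above were not tested otherwise.

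**Figure D4:**
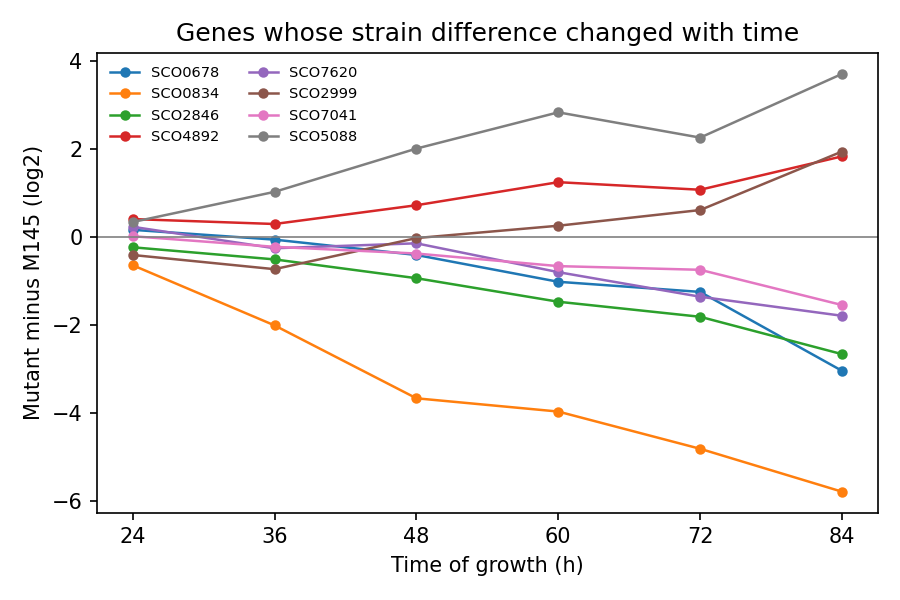
Difference between the wblA mutant and M145 (log2, y axis) against time of growth in h (x axis) for the 8 genes whose difference changed with time; each point is a difference between means of 3 cultures per strain. SCO0834 reaches -5.79 and SCO5088 3.71 at 84 h.

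In M145 alone, against 24 h, SCO0834 was at least 5.51-fold higher at 84 h (4.97 ± 0.45, adjusted p = 5.1e-08) and SCO3152 at least 3.95-fold higher (3.40 ± 0.59). The ammonium transporter gene amtB and glnK, which encodes the PII signal protein, were higher (3.03 ± 0.66, adjusted p = 0.0136, and 2.32 ± 0.51, at least 1.92-fold, adjusted p = 0.0137). SCO7657 (-2.61 ± 0.37) and SCO0428 (-2.10 ± 0.29) fell. By ratio SCO2443, SCO3644 and SCO0525 differed as well, but the direction turned with the RNA channel alone, so none is given.

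The F test over time passed for 72 genes in M145, 55 of them higher at 84 h than at 24 h. Single times against 24 h gave 0 genes at 36 h in limma (101 at an unadjusted p under 0.05), then 3 higher and 2 lower at 48 h, 8 and 6 at 60 h, 10 and 12 at 72 h and 78 and 28 at 84 h. No actinorhodin gene was among the 72. With array batch as a covariate 160 genes passed, with array weights 1204 and with the RNA channel alone 37. Of 20 named differences at 84 h, however, 12 kept the call and 8 lost it, among them glnK (SCO5584, adjusted p = 0.119). M145 cultures 2 and 3 lay in batches 2 and 3 at 24 h and in batch 4 at 84 h, so time and batch were mixed. Without M145 culture 2 or 3 of 24 h or culture 3 of 84 h the count was 44, 46 and 47.

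In the mutant, the F test over time passed for 56 genes, 48 of them higher at 84 h than at 24 h. Actinorhodin genes were among them: SCO5079, SCO5080, SCO5087, SCO5088 and SCO5089 passed, 5 of 22, and 14 adjusted over the list alone. SCO5080 rose by 3.56. Outside the lists SCO7588 rose by 4.30 and SCO4187 by 3.88, while SCO7657 (-1.67) and SCO5866 (-1.58) fell. Single times against 24 h gave 0 genes at 36 h (154 at an unadjusted p under 0.05), 1 at 48 h, 21 higher and 1 lower at 60 h, 17 and 2 at 72 h and 77 and 10 at 84 h. SCO0606, SCO0793 and SCO7657 passed over time in both strains, 3 genes where independent lists would share 0.522. Both tests used the same estimate of each gene's spread, so the lists were not independent and no conclusion is drawn from this. With array batch as a covariate 203 genes passed, with array weights 358 and with the RNA channel alone 17. Mutant culture 3 lay in batch 3 at 24 h and in batch 4 at 84 h. Culture 2 lay in batch 2 at 24 h and had 1 array in batch 4 at 84 h, so time and batch were mixed in part here too. Without mutant culture 2 or 3 of 24 h or culture 3 of 84 h the count was 33, 34 and 31.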

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

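Of the tests in this part, the join by row order, the 2-fold part of the batch test and the leaving out of single times were chosen only after the result was seen, as were the fits without the doubted arrays and within each batch.

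For 8 genes the difference between the strains changed with time by limma's F test of that difference, and their values at 24 and 84 h follow. SCO0678 went from 0.17 to -3.04 (adjusted p = 0.000153) and SCO0834 from -0.64 to -5.79 (adjusted p = 0.00034). SCO2846 went from -0.23 to -2.66 (adjusted p = 0.000875), SCO7620 from 0.24 to -1.79 (adjusted p = 0.0166) and SCO7041 from 0.02 to -1.54 (adjusted p = 0.0171). SCO4892 went from 0.41 to 1.84 (adjusted p = 0.00699), SCO2999 from -0.41 to 1.95 (adjusted p = 0.0171) and the actinorhodin gene SCO5088 from 0.34 to 3.71 (adjusted p = 0.0242). For the count of these genes chance could not be excluded, since 7 of 100 splits of the cultures, the real one among them, gave as many as the real 8 and the highest other split gave 766. Splits with several times the real count point to a structure of the cultures. With array batch as a covariate 109 genes passed, in the fit on single arrays. The RNA channel alone and the pairing of cultures as a block each gave fewer than 8.

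The deposited value table followed the array files at 24 and 36 h (r over genes 0.879 and 0.940) but less at 48, 60, 72 and 84 h (0.317, 0.251, 0.255 and 0.308). Another normalisation by the authors is argued against by the highest r over these times and 5 normalisations, 0.40, and an exchange of columns by 0 of 4 columns following another time best. On 5, 4, 6 and 7 arrays of these times the spots are listed in another order. A candidate explanation is that arrays were joined by row position. Repeating that join gave r of at least 0.847 at the 4 times, and 0.965 to 0.980 after loess. After loess r was 0.986 and 0.989 at 24 and 36 h, where all arrays share 1 order. Joined by spot position after loess, r was at most 0.378 at the 4 times, which argues against that join there. Values of single genes in this table may thus belong to other genes at those times. No biological explanation was tested, and the other steps by which the table was made stay open.

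In M145, single arrays of culture 1 at 36, 72 and 84 h and of culture 2 at 72 h had wblA at 0.05, 0.20, -0.09 and -0.21, where the other array of each culture had between 1.57 and 3.77. Arrays that hold mutant RNA are argued against by 0 of the 4 lying nearer to the mutant's mean on genes that changed at the other times, with wblA left out. A compressed range is argued against as well, since 0 of the 4 had a smaller spread of log ratios than the other array of the culture. Without these arrays the counts at 24 to 84 h were 15, 88, 98, 136, 64 and 236 and the average count 1134, all within 1.5 times of those with them. The cause of the low signal stays open, and no biological explanation was tested, since both arrays hold RNA of the same culture.

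The first principal component of the arrays' levels (25.5% of variance) followed the array batch (R squared 0.695) and the slide series (0.783) and hardly the strain (0.0388). Strain and batch were unevenly mixed from 48 h on. Of the genes called on average in cultures 2 and 3 alone, 81.9% (1274 of 1555) had the same sign in batch 1, where both strains were present at all times, beside 62.3% of all genes; leaving out 1 time gave 78.7 to 83.3%, which reaches below the 80% set in advance, so batch and strain cannot be told apart for every smaller difference. For genes changed at least 2-fold batch as the whole cause is argued against by 95.1% (155 of 163, and 92.6 to 96.9% without 1 time). Unspecific hybridisation is argued against as the whole cause by 5.76% of SCP1 probes called (16 of 278) beside 13.8% of chromosomal genes. At 2-fold or more it was 0.719% of SCP1 probes (2 called, the larger at 1.22) beside 1.51% of genes. M145 lacks SCP1, so differences without a target passed at both thresholds. Unspecific signal may therefore make up a share of the called genes, of a size not settled here. The batch test used signs only and does not bear on size: the actinorhodin median was 0.69 within batch 3 and 2.58 within batch 4, which also differed in time. What stays open is a batch share in differences under 2-fold and in the size of larger ones, a share of unspecific signal, and an effect of the deletion, the difference the design names.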

How the results depend on the processing

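Chosen after the data were seen were slide series, the fits within batches and at 24 and 36 h alone, the fit without 4 doubted arrays, and batch, pairing and left-out cultures for lists. Among values of named genes under the alternatives (single left-out cultures apart), 6870 kept direction and side of the threshold, 501 fell short of it, 120 newly passed and 6 reversed, the deposited table apart. All 6 reversed with the RNA channel alone: M145 at 84 h against 24 h in SCO0525 (1.35), SCO2443 (1.04) and SCO3644 (0.68), SCO5444 on average (0.19) and at 60 h (0.35), and SCO6505 at 60 h (0.0426); the cause was not tested. Of 215 named differences past the threshold, 134 passed with the RNA channel alone, 118 with the first and 137 with the second array of each culture, 186 after loess and 200 or more with median centring, equal-spread scaling, batch, slide series, pairing and array weights. In the deposited table, which gives no p, 5 of 141 named calls at single times had the other sign, 1 at 60 h and 4 at 84 h, where its values may belong to other genes. What signal over background limits is the low transcripts: the median gene's RNA intensity was 322 and that of negative controls 241.

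Counts that moved by over 1.5 times are given by setting; the cause was not tested except where fewer arrays or cultures, or a stricter threshold, lower the count by construction. The RNA channel alone gave 43, 59, 67, 22 and 104 genes at 36 to 84 h, 4 between times, and 37 and 17 over time in M145 and the mutant. The first array of each culture alone gave 1, 33, 22 and 87 at 24 to 60 h, 69 at 84 h, 606 on average, 2 between times and 6 and 35 over time; the second gave 22, 50, 30 and 19 at 36 to 72 h, 4 between times and 7 over time in the mutant. Array weights gave 92, 485, 168, 1012, 39 and 853 at 24 to 84 h, 1897 on average, 212 between times and 1204 and 358 over time. Array batch as a covariate gave 28, 263, 217, 290, 155 and 548 at 24 to 84 h, 109 between times and 160 and 203 over time. That fit counted the 2 arrays of a culture almost as separate replicates, so its higher counts cannot be read as differences gained by adjusting for batch. Slide series gave 19, 155, 194, 331 and 129 at 24 to 72 h, 52 between times and 155 over time in the mutant. All arrays with culture as a random block gave 29 between times and 110 and 107 over time, and leaving out the dimmest genes gave 5 between times. Only the 6 cultures of a time gave 3, 22, 0, 31, 1 and 1 at 24 to 84 h in limma, with fewer cultures to estimate the spread. On average, a 2-fold minimum left 118, batches 2, 3 and 4 alone 75, 55 and 588, and 24 and 36 h alone 117. Of 10 lists called on average 4 held with an estimated correlation. Lists called at 24, 48, 60, 72 and 84 h numbered 4, 13, 9, 7 and 7, and 2, 3, 3, 2 and 1 with an estimated correlation; the RNA channel alone gave 2, 4 and 4 at 24, 60 and 84 h, and batch 5 at 60 h. Whichever 1 culture was left out, 1, 7, 10, 4, 2 and 5 of the lists called at 24 to 84 h and 9 on average kept the call.

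The pairing of cultures as a block gave 122, 178 and 240 genes at 36, 48 and 60 h, where the numbers pair the cultures. Of the named calls it ended 1, 2, 1, 3 and 2 at 24 to 72 h: SCO1241 at 24 h, SCO0834 and SCO4253 at 36 h, SCO5080 at 48 and 72 h, SCO3224 and SCO5320 at 60 h and SCO7041 at 60 and 72 h. Where they share only a number, the block gave 418 at 84 h, 1881 on average, 3 between times and 165 and 121 over time. Of 18 cultures 17 correlated best with their own number, a hint from the data that a shared array batch could give as well. For lists the block raised the S10-spc block at 24 h past the threshold (0.164 to 0.0357) and ended the whi calls at 36 h (0.0678) and on average (0.0501) and the gas vesicle call at 84 h (0.056); it changed no other call of a list.

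Leaving out each culture in turn gave 5 to 15 genes at 24 h, 26 to 125 at 36 h, 57 to 119 at 48 h, 65 to 179 at 60 h, 12 to 83 at 72 h, 125 to 317 at 84 h, 982 to 1243 on average, 4 to 17 between times, 44 to 90 over time in M145 and 31 to 80 in the mutant. Counts moved by over 1.5 times at 24 h without M145 culture 2 (5), and at 36 h without M145 cultures 1, 2 and 3 (39, 43 and 33) and mutant cultures 1, 2 and 3 (125, 26 and 29). At 48 h they moved without M145 culture 2 (57) and mutant cultures 2 and 3 (58 and 61), and at 60 h without M145 cultures 2 and 3 (83 and 73) and mutant cultures 2 and 3 (65 and 71). At 72 h they moved without M145 cultures 2 and 3 (38 and 23) and mutant cultures 1 and 3 (26 and 12), and at 84 h without M145 cultures 2 and 3 (125 and 129) and mutant culture 3 (132). Between times they moved without M145 culture 2 (4) or mutant culture 1 (17) of 84 h, over time in M145 without its cultures 2 and 3 of 24 h (44 and 46) or 3 of 84 h (47), and in the mutant without its cultures 2 and 3 of 24 h (33 and 34) or 3 of 84 h (31).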

Other observations

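The counts of neighbouring pairs and of splits were predicted before their results were seen. No such record exists for the counts of runs, the splits that part all pairs, or the reading of single splits by batch.

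Genes that changed on average lay next to each other on the chromosome more often than shuffled gene orders gave. Neighbouring pairs called in the same direction numbered 171, against a mean of 75.0 and at most 104 in 1000 shuffles, which argues against positions without order. Runs of at least 4 such genes numbered 10, against at most 4 in the shuffles. The longest, SCO5083 to SCO5090, held 8 genes of the actinorhodin cluster with a median difference of 1.27, and SCO5071 to SCO5074 of the same cluster made another. Other runs in the fixed lists were SCO2716 to SCO2719, chaplin and rodlin genes (median -1.79), SCO0650 to SCO0654, gas vesicle genes (-0.70, with the reservation given above for the RNA channel alone), and SCO3227 to SCO3230 of the calcium-dependent antibiotic (0.77). Outside the lists SCO0584 to SCO0588 and SCO7450 to SCO7453 (median -0.91) were lower and SCO5034 to SCO5037 (0.91) and SCO4889 to SCO4892 (0.50) higher in the mutant.

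Other splits of the same cultures into equal groups were counted as a check on chance. At a single time the 10 splits are too few for a share under 0.05. At 24, 36, 48 and 60 h only 1 split, the real one, gave as many genes as the real 12, 77, 109 and 148, and the highest of the others gave 0, 0, 1 and 0. At 72 h 2 splits did (real 59, highest other 60) and at 84 h also 2 (real 225, highest other 676). The split with 676 set M145 culture 1 and mutant cultures 1 and 2 against the other 3 cultures, whose arrays all lay in array batch 4, as did 1 array of mutant culture 2. It thus followed the batch in part, and with batch as a covariate the real count was 548. The split with 60 at 72 h set M145 culture 1 and mutant cultures 1 and 3 against the rest and also followed the batch in part. The real count with batch as a covariate was 155 there. Both counts with batch as a covariate came from fits on single arrays and are not comparable with those of the splits. From 24 to 72 h, the 3 other splits of each time that also part all 3 pairs of cultures gave 0 genes each in limma. The remaining splits keep 1 pair on each side.

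For the average over times 2 of 100 splits, the real one among them, gave as many genes as the real 1079 (highest other 1311), a share under 0.05. For time in the mutant 1 of 100 did, the real one itself (real 56, highest other 35). For time in M145 5 of 100 did, the real one among them (real 72, highest other 266), which is not under 0.05. The splits were drawn without regard to batch or pairing, so they cannot part strain or time from these. Splits that call several times the real count point to a structure of the cultures.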
